A study of Drosophila melanogaster with 10 samples.

How the data were processed

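Polyadenylated RNA was sequenced from whole adult male Drosophila melanogaster, with 5 flies pooled per sample, aged 5 to 10 days after eclosion. Per the labels' protocols, flies were lysed in 200 µl of TRIzol, libraries were made with a strand-preserving mRNA kit from 250 ng of total RNA with fragmentation for 10 minutes at 94 °C and 14 PCR cycles, and they were sequenced on an Illumina NextSeq 500 without spike-ins. The 5 control samples carried the c564 driver alone, and the 5 knockdown samples carried the driver and a UAS transgene encoding an RNA interference hairpin against Mef2. The labels call the 5 samples of a group biological replicates. The control flies carried no hairpin transgene, so the groups differ in the transgene and its insertion as well as in Mef2. The series' design text places the hairpin opposite the driver, and the sample labels place it on another chromosome, so the site of the insertion is not known here.

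The authors deposited 1 table of raw counts per gene, whole numbers for 17559 gene identifiers, with no row that names no gene. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.4.0j, featureCounts and limma, and the genome was BDGP6. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Of the 111 replication-dependent histone copies, which are near-identical in sequence, 108 had a count of 0 in all 10 libraries. Transcripts without a poly(A) tail would also be at 0 in these libraries, so the zeros do not show how such reads were treated. As that treatment is not given, the counts of near-identical copies are treated as uncertain. Where strand was not used, overlapping genes on opposite strands cannot be told apart. Among the 69 genes that the rule below took, exons of another gene overlap those of Hsp68, Hsp70Ab, BomS4, PGRP-SD, SPE, et, Lsd-1, Lip3, CG9485, Pgd, ScsbetaA, Gp93, Jon44E, Syx1A and roX1.

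Identifiers were paired with symbols and coordinates through Ensembl annotation release 115 of BDGP6. Of the 17559 identifiers, 17253 had a symbol and coordinates and 306 had neither. Of 534 genes placed on lists, 516 were paired with a row. The other 18 were left out because their current identifiers are not in the table, among them Drs, InR, FASN1, Pdi, PPO1, wupA, para, VAChT and nos. No older identifier was guessed.

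Total counts were 43823883 to 102851945 per library. A count of 3, taken as the floor, equals 0.0292 to 0.0685 CPM. Such floors cover counting error only, because PCR copies without molecular identifiers are not independent molecules. No 2 libraries of a group agreed within sampling noise, since the chi-square of their counts divided by its degrees of freedom was 7.10 or more over genes with a count of at least 10.

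The test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its minimum count of 10, a quasi-likelihood fit on group alone over all 10 libraries, and Benjamini-Hochberg adjustment over 13928 tested genes. A gene was called at an adjusted p under 0.05. Standard errors were obtained as the size of the log2 fold change divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD over 5 libraries. In simulated counts drawn for these libraries, 200 genes were changed and a further list of genes was raised. The same steps recovered 22% of genes changed 1.25-fold, 78% at 1.5-fold, 88% at 2-fold and 98% at 4-fold. Each share is out of 50 genes among 13859 tested, and 4.94% of the calls were false. Genes were drawn independently and without sets of replicates, so these shares may not hold in the real libraries.

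There were 20 function lists, 11 cell type lists and 1 check list. They were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, again with an estimated correlation, and with fry, each two-sided and adjusted over the 32 lists. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took Mef2, w, roX1 and roX2 whatever their p. It added the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the groups. It also added the 2 members with the smallest adjusted p of each function list and 1 of each cell type list. This gave 69 genes. Other list members named below were chosen after their values were seen.

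The labels number the samples 1 to 5 in both groups. Deviations of same-numbered samples from their group means correlated at 0.16 to 0.28, above the bound of 0.1 in every pair. By that bound the number was used as a block in an alternative fit, while the main fit used neither number nor set. A pairing by number would rest on the data alone, since no label says that a number marks a shared day or batch. Samples with another number within the same set, replicates 1 to 3 or replicates 4 and 5, correlated at 0.09 to 0.34, and samples of different sets at -0.31 to -0.10. Read from the control libraries, only 2 of the 5 pairs correlated best within their own number. The bound therefore does not tell a pair from a set. The principal components separated the same 2 sets, which the labels do not name. The set was therefore used as a covariate, as a subset and in an interaction with group. These fits were chosen after the data were seen.

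Alternatives were DESeq2 size factors, upper-quartile and total-count scaling, no filter beyond 1 count, a filter of CPM of at least 1 in 5 libraries, the DESeq2 1.42.0 Wald test, limma voom with and without quality weights, the replicate number as a block, leaving out each library in turn, and leaving out the reproductive tract lists with the 20 most abundant genes. Alternatives added later were the set fits, counts thinned to the smallest library and removal of each library's trend of log2 CPM on exon length. No check of GC content was made, because no genome sequence was used here.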

Results

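Gene expression was measured by RNA sequencing in whole adult male flies to examine the effect of knocking down Mef2, a MADS-box transcription factor known for muscle differentiation, in the fat body, the insect organ of nutrient storage and humoral immunity. The c564 driver expresses GAL4 in the fat body and in some other tissues, and GAL4 activates the hairpin transgene. There were 5 control libraries with driver alone and 5 knockdown libraries with driver and hairpin. Total counts were 49779353, 56472658, 52662072, 50218486 and 45231822 in control replicates 1 to 5, and 50926765, 102851945, 48196161, 43823883 and 63728814 in knockdown replicates 1 to 5. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and values after ± are SDs over 5 libraries unless named as SE.

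Mef2 (FBgn0011656, chromosome 2R, 9913496 to 9958858, BDGP6) was lower in the knockdown libraries. Its level was 93.6 ± 4.6 CPM in control and 79.3 ± 5.1 CPM in knockdown, a log2 fold change of -0.24 (SE 0.06, adjusted p = 0.0149). The control libraries held 95.1, 92.7, 100.7, 90.7 and 88.9 CPM and the knockdown libraries 75.9, 78.7, 73.6, 81.6 and 86.6 CPM, so the groups did not overlap. The fall was larger within replicates 1 to 3 (-0.34) than within replicates 4 and 5 (-0.09), and this difference passed the interaction test (adjusted p = 0.0425). In a fit of replicates 4 and 5 alone, chosen after the data were seen, the change was -0.12 and was not called. Counts from the whole fly include tissues outside the driver's range, and any hairpin transcript would add to the counts of Mef2. The eye pigment transporter gene w (chromosome X, 2790599 to 2796466), whose mini-gene marks many fly transgenes, rose from 54.6 ± 4.7 to 399 ± 106 CPM (log2 2.87, SE 0.16, adjusted p = 8.61e-07). Of the dosage compensation RNAs of males, roX2 was slightly higher (log2 0.29, SE 0.08, adjusted p = 0.0344). This call was lost (adjusted p 0.0541 to 0.0799) without control replicate 2, 4 or 5 or without knockdown replicate 3, 4 or 5. It was also lost with upper-quartile scaling (adjusted p = 0.0628), with no filter beyond 1 count (adjusted p = 0.0512) and in replicates 1 to 3 alone (adjusted p = 0.108). The change of roX2 was 0.15 within replicates 1 to 3 and 0.51 within replicates 4 and 5 (interaction adjusted p = 0.036). roX1 had a log2 change of -0.11 (SE 0.07, adjusted p = 0.298), which was called without knockdown replicate 5 (adjusted p = 0.0454), with voom quality weights (-0.20, adjusted p = 0.00263) and in replicates 1 to 3 alone (-0.21, adjusted p = 0.00382).

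Heat shock proteins, detoxification enzymes, and genes of immune recognition and signalling were among those higher in knockdown, and 3 of 4 oenocyte markers were lower. Across all tested genes, 1549 were higher and 768 lower in knockdown, 16.6% of the 13928 tested. A change of at least 2-fold was reached by 198 of the higher and 48 of the lower genes. In 2596 genes (18.6%) the 5 knockdown and 5 control libraries did not overlap, where chance gives 0.794%. That chance share takes all arrangements of the libraries as equally likely and ignores the sets and numbering of replicates. Higher genes made up 66.9% of the calls with TMM, 53.2% (1301 higher, 1145 lower) with upper-quartile scaling, and 47.7% (1832 higher, 2011 lower) in replicates 4 and 5 alone. The number of higher genes was 952, 1001 and 853 without control replicate 1, 2 or 3, and that of lower genes 473, 444, 414 and 454 without control replicate 1, 3, 4 or 5.

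The largest rises under the rule were in CG10814 (log2 6.48, SE 0.67, adjusted p = 0.000102) and the cytochrome P450 gene Cyp4p2 (log2 6.35, SE 0.21, adjusted p = 2.25e-08). CG10814 (chromosome 2R, 13375975 to 13377731) went from 0.312 ± 0.346 to 26.8 ± 17.6 CPM, and Cyp4p2 (chromosome 2R, 9237512 to 9239831) from 0.302 ± 0.088 to 25.0 ± 5.5 CPM. FBgn0028519, which has no symbol in the annotation, rose by a log2 of 4.81 (SE 0.75). The other large rises were heat shock genes. Hsp68 (chromosome 3R, 24055080 to 24057310) rose from 55.3 ± 2.1 to 739 ± 145 CPM (log2 3.74, SE 0.14, adjusted p = 2.25e-08). Log2 changes of the Hsp70 copies were 5.10 for Hsp70Bb, 4.40 for Hsp70Ab, 3.93 for Hsp70Bc and 3.88 for Hsp70Ba, and because these copies are near-identical the split of reads among them is uncertain.

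The largest falls were in whe (log2 -4.16, SE 0.14, adjusted p = 2.25e-08) and lcs (log2 -3.73, SE 0.22, adjusted p = 1.06e-06). whe (chromosome X, 21402339 to 21402772) dropped from 1059 ± 121 to 59.2 ± 10.6 CPM, and lcs (chromosome X, 21396727 to 21397316), 5.02 kb away, from 1037 ± 140 to 78.2 ± 25.7 CPM. CG16826 (chromosome 2L, 13347773 to 13349020), the most abundant of the 8, fell from 2373 ± 119 to 377 ± 92 CPM (log2 -2.65). CG34212, CG45080 and CG33109 each had a log2 change of -3.11, CG43680 of -2.78 and CG17192 of -2.12. All 8 fell in both sets of replicates, which the rule's demand of no overlap between the groups fixed in advance.

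**Figure D1:**
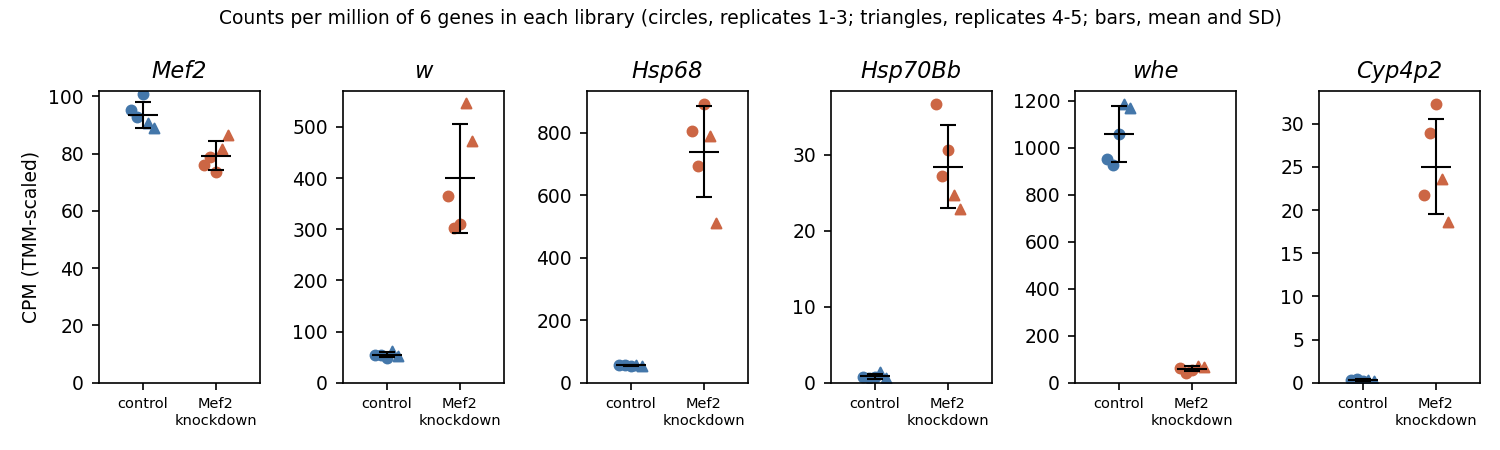
CPM (TMM-scaled, vertical axes from 0) of Mef2, w, Hsp68, Hsp70Bb, whe and Cyp4p2 in each of the 5 control (blue) and 5 knockdown (orange) libraries, with mean and SD as bars, circles for replicates 1 to 3 and triangles for replicates 4 and 5. The groups do not overlap for any of the 6 genes, with Mef2 at 93.6 against 79.3 CPM and Hsp68 at 55.3 against 739 CPM. The largest rises and falls, which hold Hsp68, Hsp70Bb, whe and Cyp4p2, were taken only from genes without overlap.

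Heat shock proteins, the chaperones induced by misfolded protein, rose as a group. Of 12 tested members 11 were higher and none lower, also when adjusted over the list alone, with a median log2 change of 2.49. The rise reached the small heat shock proteins Hsp26 (2.70), Hsp23 (2.28) and Hsp27 (1.23), the Hsp70 cochaperone DnaJ-1 (1.11), Hsp83 (0.92) and the mitochondrial chaperonin Hsp60A (0.71). The median was 2.39 within replicates 1 to 3 and 2.58 within replicates 4 and 5, but the effect differed between the sets in 6 of the 12 members. Hsp70Ba had log2 changes of 4.88 and 2.56 (interaction adjusted p = 0.00471) and Hsp70Bc of 4.49 and 3.04 (interaction adjusted p = 0.0109). This was the one list of 32 whose camera call (adjusted p = 1.43e-15) held with an estimated correlation (adjusted p = 0.0204). In the list of endoplasmic reticulum folding and secretion, 6 of 14 members were higher (10 adjusted over the list alone) and none lower (camera adjusted p = 0.000791, but adjusted p = 0.665 with an estimated correlation). They included the lumenal chaperones Hsc70-3 (log2 0.64, SE 0.15, adjusted p = 0.0146) and Gp93 (log2 0.47, SE 0.11, adjusted p = 0.0149) and the unfolded protein response factor Xbp1 (0.61). The count was 3 without control replicate 1 or 3. The median was 0.16 within replicates 1 to 3 and 0.36 within replicates 4 and 5.

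Some immune genes were higher in knockdown, most of them in recognition and signalling, the largest of the 4 lists. Median log2 changes were 0.30 for recognition and signalling, 1.10 for the Bomanins, 1.01 for the antimicrobial peptides and 0.14 for JAK-STAT. Of 34 Toll and Imd recognition and signalling genes, 13 were higher and none lower (24 adjusted over the list alone, 22 with the replicate number as a block). PGRP-SD, a peptidoglycan recognition protein, rose from 21.4 ± 6.8 to 63.2 ± 16.2 CPM (log2 1.57, SE 0.22, adjusted p = 0.000833), and SPE, the protease that activates the Toll ligand, rose by a log2 of 0.58 (SE 0.09, adjusted p = 0.00134). PGRP-SA (1.31) and the NF-kappaB factors Rel (0.72) and Dif (0.29) were also called. Among the Bomanins and related peptides, 6 of 12 were higher and none lower (8 adjusted over the list alone), led by BomS4 (log2 0.69, SE 0.11, adjusted p = 0.00191) and the serine protease homolog SPH93 (log2 3.16, SE 0.52, adjusted p = 0.00216). Of 17 antimicrobial peptides, 2 were higher and 1 lower (4 and 1 adjusted over the list alone, 6 and 1 with the block). DptA, a diptericin, rose from 2.81 ± 1.86 to 13.2 ± 3.8 CPM (log2 2.24, adjusted p = 0.00399), while Drsl4 fell from 89.2 ± 11.8 to 27.2 ± 13.8 CPM (log2 -1.72, adjusted p = 0.00469). Of 16 JAK-STAT and Turandot genes, 2 were higher (5 higher and 1 lower adjusted over the list alone), namely the receptor-like repressor et (log2 0.67, SE 0.07, adjusted p = 0.000142) and the thioester protein Tep4 (log2 0.85, SE 0.11, adjusted p = 0.000635). By camera the adjusted p was 6.38e-08 for recognition and signalling and 7.74e-05 for the Bomanins. Both calls were lost with an estimated correlation (adjusted p = 0.594 for each). The antimicrobial peptides (adjusted p = 0.0772) and JAK-STAT genes (adjusted p = 0.0524) were not called, but were called with the block (adjusted p = 0.0395 and 0.0366). With an estimated correlation and no block they had adjusted p = 0.742 and 0.594. With the set as a covariate the antimicrobial peptides were not called (adjusted p = 0.123) and the JAK-STAT genes were (adjusted p = 0.0337). With that covariate and an estimated correlation, camera called neither (adjusted p = 0.768 and 0.303). Medians within replicates 1 to 3 and within replicates 4 and 5 were 0.20 and 0.41 for recognition and signalling, 1.04 and 1.03 for the Bomanins, 1.58 and 0.23 for the antimicrobial peptides, and 0.26 and 0.02 for JAK-STAT. Without control replicate 4, 4 antimicrobial peptides and 4 JAK-STAT genes were higher. Without knockdown replicate 4, 3 antimicrobial peptides were lower, and without knockdown replicate 1, 1 JAK-STAT gene was lower. Hemocyte markers were also higher in knockdown, as given below.

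Carbohydrate enzymes rose in part. Of 11 glycogen and trehalose genes, 3 were higher and none lower (5 adjusted over the list alone, 5 with the block). The glycogen debranching enzyme CG9485 had a log2 change of 1.37 (SE 0.26, adjusted p = 0.00515), the branching enzyme AGBE of 1.07 (SE 0.29, adjusted p = 0.031) and the trehalose transporter Tret1-1 of 0.43. Within replicates 1 to 3 the changes of CG9485 and AGBE were 1.65 and 1.49, and within replicates 4 and 5 they were 0.72 and 0.10. The interaction passed for both (adjusted p = 0.0429 and 0.0117). The call of AGBE was lost (adjusted p 0.0576 to 0.0806) without any 1 of control replicates 1 to 5 or knockdown replicate 1 or 2. It was also lost with limma voom (adjusted p = 0.061). The list count was 1 with limma voom and under each of these omissions and 6 without knockdown replicate 4. Of 16 genes of glycolysis and gluconeogenesis, 4 were higher and none lower (4 higher and 1 lower adjusted over the list alone, and with the block). Pepck2, a phosphoenolpyruvate carboxykinase, rose from 25.7 ± 2.7 to 68.5 ± 3.6 CPM (log2 1.41, SE 0.07, adjusted p = 4.17e-07). Lactate dehydrogenase, Ldh, rose from 61.8 ± 3.0 to 108.5 ± 9.6 CPM (log2 0.81, SE 0.07, adjusted p = 1.7e-05). Without knockdown replicate 1, 1 member was lower. Among 9 genes of the pentose phosphate pathway and NADPH supply, 2 were lower and 1 higher (3 and 1 adjusted over the list alone). The malic enzyme Men (log2 -0.45, SE 0.07, adjusted p = 0.00147) and phosphogluconate dehydrogenase Pgd (log2 -0.35, SE 0.08, adjusted p = 0.0149) fell, and the 1 higher gene, Men-b, was not called without control replicate 1 or 3 or without knockdown replicate 5. The camera calls of the glycogen list (adjusted p = 0.0167) and the glycolysis list (adjusted p = 0.0321) were lost with an estimated correlation (adjusted p = 0.665 and 0.727). The pentose phosphate list was not called (adjusted p = 0.226). Medians in the 2 sets, replicates 1 to 3 first, were 0.42 and 0.11 for glycogen, 0.22 and 0.02 for glycolysis, and -0.10 and -0.24 for the pentose phosphate list.

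Lipid genes moved in both directions. Of 17 genes of lipid synthesis and storage, 4 were higher and 4 lower (4 and 4 adjusted over the list alone). The stearoyl-CoA desaturase Desat1 fell from 3482 ± 154 to 2099 ± 394 CPM (log2 -0.73, SE 0.12, adjusted p = 0.00258), and Lsd-1, the perilipin of lipid droplets, from 295 ± 23 to 174 ± 38 CPM (log2 -0.76, SE 0.14, adjusted p = 0.00408). Acetyl-CoA carboxylase, ACC (-0.54), and the acyltransferase mino (-0.50) also fell, whereas the acyltransferases Dgat2 (1.43) and mdy (0.48) and the regulator SREBP (0.50) rose. The number higher was 1 without control replicate 1, 2, 3 or 4 or knockdown replicate 5, and 2 without control replicate 5 or knockdown replicate 4. Of 16 genes of lipid breakdown, 3 were higher and 3 lower (4 and 4 adjusted over the list alone, 3 and 1 with the block). The lipases Lip4 (log2 0.98, SE 0.22, adjusted p = 0.0135) and Lip3 (log2 1.91, SE 0.44, adjusted p = 0.0145) rose, and the mitochondrial genes whd (-0.29), Mtpalpha (-0.25) and Mtpbeta (-0.21) fell. The number lower was 1 without control replicate 3 or any 1 of knockdown replicates 2 to 5, and 0 without control replicate 4 or 5. Neither list was called by camera (adjusted p = 0.367 and 0.849). Medians within replicates 1 to 3 and within replicates 4 and 5 were -0.01 and 0.03 for synthesis, and 0.05 and -0.04 for breakdown.

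Detoxification enzymes rose, with 12 of 20 higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 4.68e-05, but adjusted p = 0.594 with an estimated correlation). Cyp6a2 rose from 39.8 ± 3.5 to 110.4 ± 14.0 CPM (log2 1.47, SE 0.09, adjusted p = 1.76e-06), and Cyp28a5 from 66.4 ± 2.0 to 222 ± 49 CPM (log2 1.74, SE 0.13, adjusted p = 6.33e-06). The glutathione transferases GstD2 (2.78) and GstE1 (2.48) rose more. Cyp12d1-p (-0.72) and Cyp6w1 (-0.47) fell. The number lower was 0 without control replicate 4 and 1 without control replicate 5. The median was 0.70 within replicates 1 to 3 and 0.40 within replicates 4 and 5. Of 14 genes of amino acid and one-carbon metabolism, 6 were higher and none lower (6 higher and 1 lower adjusted over the list alone, 8 and 1 with the block). Cystathionine beta-synthase, Cbs, rose by a log2 of 1.19 (SE 0.22, adjusted p = 0.00398), the glutamine synthetase Gs1 by 0.78 (SE 0.14, adjusted p = 0.00398) and sarcosine dehydrogenase, Sardh, by 1.35. The number higher was 3 without control replicate 1 or 3, and 1 gene was lower without control replicate 4 or without knockdown replicate 2. Medians were 0.31 and 0.27 in the 2 sets (camera adjusted p = 0.00308, but adjusted p = 0.594 with an estimated correlation).

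Autophagy genes rose in part, with 6 of 13 higher and none lower (6 adjusted over the list alone). Atg7 rose by a log2 of 0.62 (SE 0.06, adjusted p = 4.55e-05), Atg13 by 0.44 (SE 0.05, adjusted p = 0.000392) and the cargo receptor ref(2)P by 0.99. The median was 0.10 within replicates 1 to 3 and 0.37 within replicates 4 and 5 (camera adjusted p = 0.000656, but adjusted p = 0.433 with an estimated correlation). Insulin, FOXO and nutrient response genes went both ways, with 3 of 17 higher and 3 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.824). The activin ligand daw (log2 -0.78, SE 0.13, adjusted p = 0.00274) and the insulin-like peptides Ilp5 (log2 -0.72, SE 0.13, adjusted p = 0.00456) and Ilp2 (-0.35) fell, and Ilp6, an insulin-like peptide made in the fat body, rose (0.70). The number higher was 0 without control replicate 2, 3, 4 or 5 and 1 without knockdown replicate 1, 4 or 5. Medians were -0.08 and 0.39 in the 2 sets.

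Mitochondrial respiration genes did not pass the test in edgeR over all libraries. None of 16 TCA cycle genes and none of 30 oxidative phosphorylation genes was called, nor any adjusted over the list alone. At an unadjusted p under 0.05 there were 1 and 2 such genes. The DESeq2 Wald test called 1 TCA gene lower and 1 oxidative phosphorylation gene higher, limma voom called none, and voom with quality weights called 2 TCA genes higher and 1 lower and 1 oxidative phosphorylation gene higher. With the set as a covariate, edgeR called ScsbetaA (adjusted p = 0.0334) and ND-49 (adjusted p = 0.0283). The smallest adjusted p-values were those of ScsbetaA (log2 -0.16, SE 0.06, adjusted p = 0.087) and Mdh1 (0.20, SE 0.11, adjusted p = 0.198), and of ND-49 (0.16, SE 0.06, adjusted p = 0.0651) and COX7A (-0.13, SE 0.06, adjusted p = 0.121). Camera gave adjusted p = 0.975 and 0.824, with the direction down although both medians were slightly above 0 (0.02 each). Medians in the 2 sets were 0.03 and -0.01 for the TCA cycle, and 0.06 and -0.09 for oxidative phosphorylation. Within replicates 1 to 3, 1 TCA gene was higher, and within replicates 4 and 5, 1 TCA gene and 5 oxidative phosphorylation genes were lower and 1 of the latter higher. Of 27 cytosolic ribosomal protein genes, 4 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.0363, but adjusted p = 0.776 with an estimated correlation). RpL5 rose by a log2 of 0.28 (SE 0.05, adjusted p = 0.00435) and RpS4 fell by 0.31 (SE 0.07, adjusted p = 0.0154). The number higher was 2 with DESeq2 size factors and 1 with upper-quartile or total-count scaling. It was 1 without control replicate 1, 2, 3 or 4 or knockdown replicate 4, and 2 without control replicate 5 or knockdown replicate 1, 2 or 5. Medians in the sets were 0.06 and 0.18. No gene of 13 for ribosome biogenesis was called over all libraries by edgeR, DESeq2 or limma voom, 1 was higher with the set as a covariate, and none had an unadjusted p under 0.05 (camera adjusted p = 0.221), with log2 changes of 0.23 for Nop56 (SE 0.12, adjusted p = 0.198) and 0.21 for pit (SE 0.12, adjusted p = 0.217). Within replicates 4 and 5, however, 12 were higher, and within replicates 1 to 3 1 was lower, with list medians of 0.44 and -0.08. Of 9 clock genes, Clk was lower (log2 -0.25, SE 0.04, adjusted p = 0.00331) and cyc higher (log2 0.34, SE 0.10, adjusted p = 0.0316), likewise adjusted over the list alone. The call of cyc was lost (adjusted p 0.0562 to 0.0803) without any 1 of control replicates 1 to 5 or without knockdown replicate 5. The clock list was not called (camera adjusted p = 0.55), with medians of 0.02 and 0.26 in the sets.

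**Figure D2:**
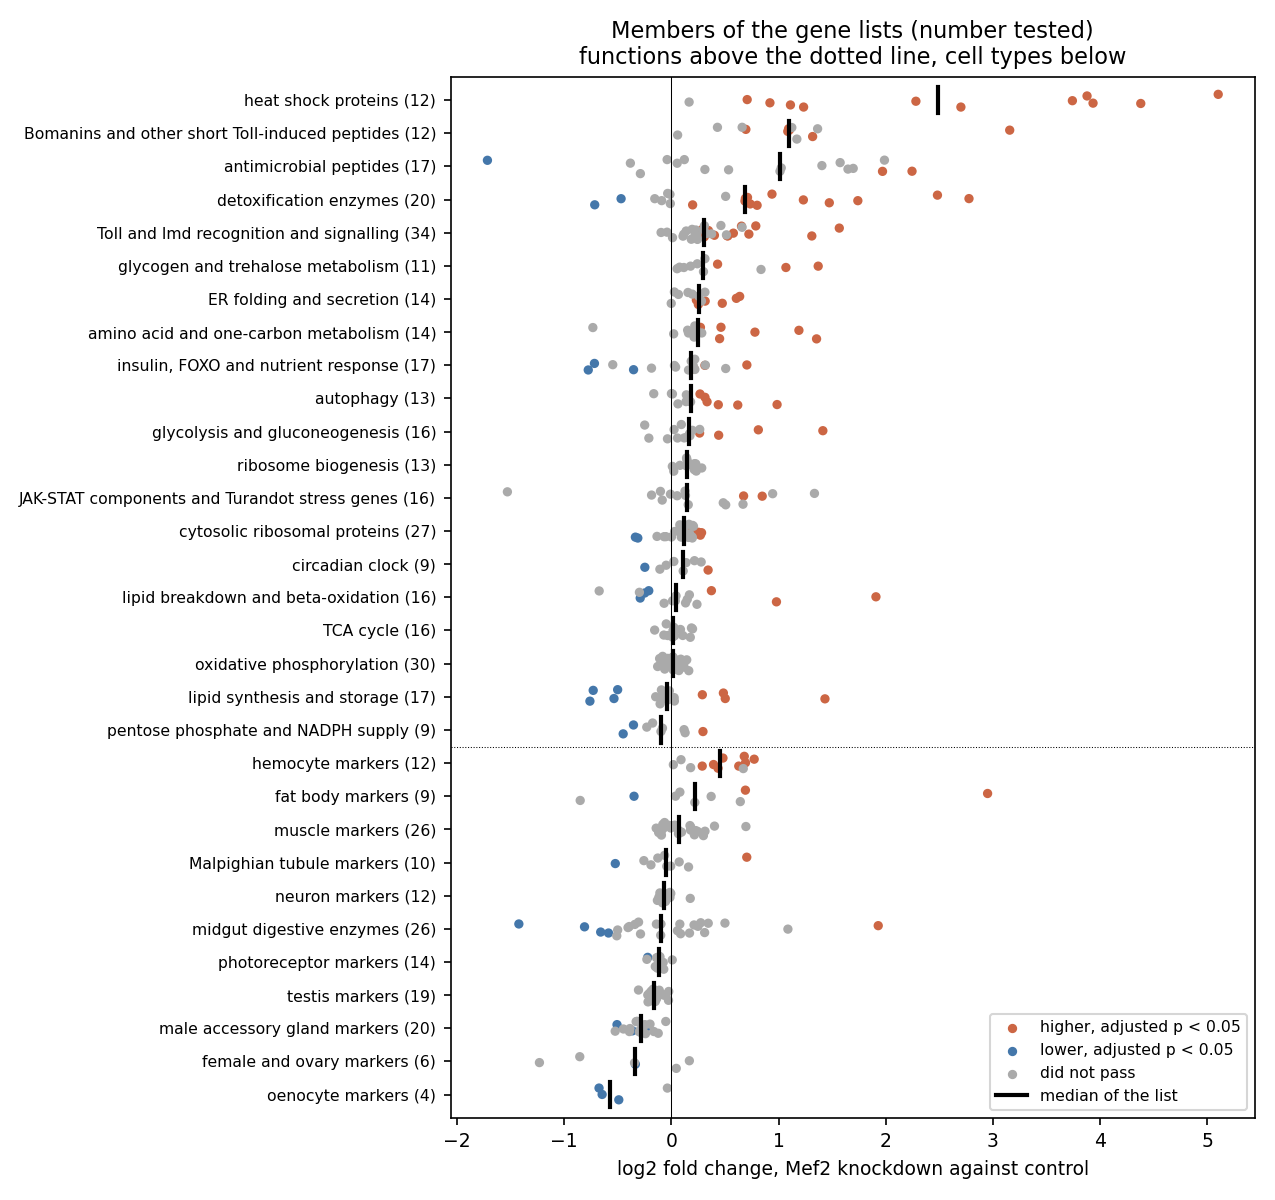
Log2 fold change of each tested member of the 20 function lists (above the dotted line) and 11 cell type lists (below it), colored by call in edgeR, with the list median as a black bar and the number tested in parentheses. Heat shock proteins have the highest median at 2.49 and oenocyte markers the lowest at -0.57.

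Among cell type markers, camera called those of hemocytes higher and those of oenocytes, testis, accessory gland and photoreceptors lower at its preset correlation, and none of these calls held with an estimated correlation. Of 12 hemocyte markers, 8 were higher and none lower (9 adjusted over the list alone, camera adjusted p = 0.000179, but adjusted p = 0.374 with an estimated correlation), led by the scavenger receptor Sr-CI (log2 0.63, SE 0.08, adjusted p = 0.000464), and the count was 5 without control replicate 3. The collagen IV genes Col4a1 (0.77) and vkg (0.69), which the fat body also expresses, were among them. Of 4 oenocyte markers, 3 were lower (3 adjusted over the list alone, camera adjusted p = 0.00625, but adjusted p = 0.594 with an estimated correlation), including the fatty acid synthase FASN2 (log2 -0.65, SE 0.10, adjusted p = 0.00136) and the hydrocarbon-forming Cyp4g1 (-0.68). Of 20 accessory gland markers, 3 were lower (8 adjusted over the list alone, 8 with the block, camera adjusted p = 4.29e-05, but adjusted p = 0.594 with an estimated correlation), with Acp53C14c at a log2 of -0.51 (SE 0.13, adjusted p = 0.0192), a call lost without control replicate 1 (adjusted p = 0.05). The count was 0 without control replicate 1, 1 without control replicate 2 or 3 or knockdown replicate 2 or 3, and 7 without knockdown replicate 4. It was 17 with voom quality weights, 17 in replicates 1 to 3 alone and 2 in replicates 4 and 5 alone. No testis marker of 19 was called by edgeR over all libraries, nor adjusted over the list alone, although the list was (camera adjusted p = 0.000512). At an unadjusted p under 0.05 there were 8, and 6 were lower with DESeq2, 1 with limma voom, with or without quality weights, 1 with the block and 8 with the set as a covariate. Within replicates 4 and 5 edgeR called 14 lower (8 in those libraries alone), and within replicates 1 to 3 none. The list had adjusted p = 0.665 with an estimated correlation. betaTub85D, a testis tubulin, had a log2 change of -0.22 (SE 0.07, adjusted p = 0.0564), called without knockdown replicate 1 (adjusted p = 0.0493) or 3 (adjusted p = 0.0415), with upper-quartile scaling (adjusted p = 0.0419) and with the set as a covariate (adjusted p = 0.0145). Of 14 photoreceptor markers, 1 was lower, Arr1 (log2 -0.22, SE 0.07, adjusted p = 0.039), with none adjusted over the list alone, 2 with the block and 8 with voom quality weights (camera adjusted p = 0.00849, but adjusted p = 0.594 with an estimated correlation). Arr1 was lost (adjusted p 0.0562 to 0.0854) without any 1 of control replicates 1 to 5 or of knockdown replicates 1 to 3, and 3 members were lower without knockdown replicate 4 or 5. In replicates 1 to 3 alone 12 were lower, and in replicates 4 and 5 alone none.

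The other cell type lists were not called by camera. Of 9 fat body markers, 2 were higher and 1 lower (4 and 1 adjusted over the list alone, 2 and 2 with the block, camera adjusted p = 0.392). The lipid transfer protein gene Mtp rose by a log2 of 0.69 (SE 0.10, adjusted p = 0.00119), Fbp2 by 2.95, and to fell by 0.35, a call absent without control replicate 2 or 4. No muscle marker of 26 was called by edgeR (camera adjusted p = 0.515), nor adjusted over the list alone, with 2 at an unadjusted p under 0.05, 1 higher with DESeq2 or limma voom, and 2 with quality weights or the set as a covariate. TpnC73F, a troponin C, had a log2 change of 0.30 (SE 0.09, adjusted p = 0.0501), called without control replicate 1 (adjusted p = 0.0371) or 2 (adjusted p = 0.0401) and with DESeq2 size factors (adjusted p = 0.0487). No neuron marker of 12 was called over all libraries by edgeR, DESeq2 or limma voom (camera adjusted p = 0.29), nor adjusted over the list alone, with 1 at an unadjusted p under 0.05, and voom with quality weights called 1 higher and 1 lower. In replicates 1 to 3 alone edgeR called 1 higher and 7 lower, and in replicates 4 and 5 alone none. Syx1A, a synaptic syntaxin, had a log2 change of 0.18 (SE 0.07, adjusted p = 0.114), called without knockdown replicate 4 (adjusted p = 0.0199), and 1 neuron marker was lower without knockdown replicate 5. Of 26 midgut enzymes, 1 was higher, Jon44E (log2 1.93, SE 0.27, adjusted p = 0.000818), and 4 were lower (1 and 5 adjusted over the list alone, 2 and 6 with the block, camera adjusted p = 0.214), and without knockdown replicate 4 these were 2 and 9. They were 4 and 11 with voom quality weights, 12 and 9 in replicates 1 to 3 alone, and 1 and 3 in replicates 4 and 5 alone. Of 10 Malpighian tubule markers, Uro was higher (0.70) and the transporter Oatp58Db lower (log2 -0.52, SE 0.05, adjusted p = 0.0001), likewise adjusted over the list alone, with 2 lower under the block or without control replicate 5 (camera adjusted p = 0.358). Of 6 female and ovary genes, Yp3 was lower (log2 -0.34, SE 0.07, adjusted p = 0.00619), likewise adjusted over the list alone, with 2 lower under the block (camera adjusted p = 0.216).

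Medians of the cell type lists within replicates 1 to 3 and within replicates 4 and 5 were 0.50 and 0.49 for hemocytes, -0.47 and -0.69 for oenocytes, -0.28 and -0.28 for accessory gland, -0.05 and -0.32 for testis, and -0.19 and -0.02 for photoreceptors. They were 0.51 and -0.24 for fat body, 0.11 and 0.08 for muscle, -0.14 and 0.05 for neurons, -0.05 and -0.37 for midgut, -0.09 and -0.02 for Malpighian tubules, and -0.30 and -0.44 for the female and ovary genes. In a fit of all libraries with a spread shared between the sets, the numbers higher and lower differed most for 5 lists. These were photoreceptors (0 and 10 against 0 and 0), testis (0 and 0 against 0 and 14), fat body (4 and 1 against 1 and 4), midgut (6 and 4 against 1 and 4) and muscle (0 and 0 against 3 and 4). In fits of each set alone the first 4 still differed, and muscle had 1 and 1 in both. There, accessory gland (0 and 17 against 0 and 2) and neurons (1 and 7 against 0 and 0) differed as well.

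The libraries of both groups fell into sets, replicates 1 to 3 and replicates 4 and 5. Knockdown replicates 4 and 5 differed from each other more than any other pair within a set. Their chi-square over its degrees of freedom was 69.74, against 7.10 to 19.97 in the other such pairs. Across sets it was 43.17 to 82.1 in control and 82.24 to 182.7 in knockdown. Effects within replicates 4 and 5 therefore rest on 2 unlike knockdown libraries, with AGBE, for example, at 124.1 and 195.4 CPM. The first principal component (48.6% of the variance) separated knockdown from control in both sets, and the second (19.9%) separated the sets. Each also held part of the other difference. On the first, knockdown replicates 4 and 5 (39.9 and 35.6) lay beyond knockdown replicates 1 to 3 (9.4 to 10.9). On the second, the groups lay apart within replicates 1 to 3 (control -1.9 to 3.2, knockdown 19.7 to 21.0). Genes higher and lower numbered 1622 and 743 within replicates 1 to 3 and 3450 and 3016 within replicates 4 and 5, in a fit with a shared spread. In fits of each set alone the numbers were closer, 2150 and 1386 against 1832 and 2011. Genes called within both sets had the same sign in 1684 cases and opposite signs in 52. At least 2-fold in both sets, 135 genes were higher and 29 lower. With the set as a covariate, 2687 genes were higher and 2084 lower, and these included all 2317 genes called over the 10 libraries. The sets are balanced over the groups and were read from these same libraries, so that overlap was likely in advance. Mef2, w, AGBE, CG9485, DptA, Drsl4, Cbs and Lip4 were among 21 of the 69 named genes whose effect differed between the sets. Cbs had a log2 change of 0.72 within replicates 1 to 3 and 1.70 within replicates 4 and 5 (interaction adjusted p = 0.00471), and Drsl4 of -1.40 and -2.62 (interaction adjusted p = 0.00699). The signs were opposite in 2 of the 21, Mdh1 (0.43 and -0.17) and Nop56 (-0.04 and 0.58), neither of which was called over the 10 libraries.

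**Figure D3:**
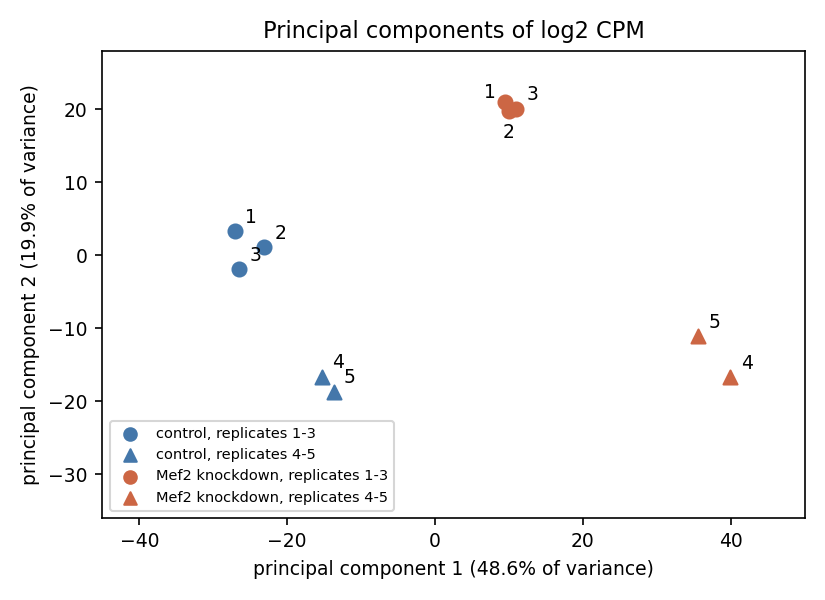
First and second principal component of log2 CPM for the 10 libraries, numbered by replicate, with control in blue, knockdown in orange, circles for replicates 1 to 3 and triangles for replicates 4 and 5. The first component (48.6%) parts the groups and the second (19.9%) parts the sets, but each also holds part of the other difference.

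**Figure D4:**
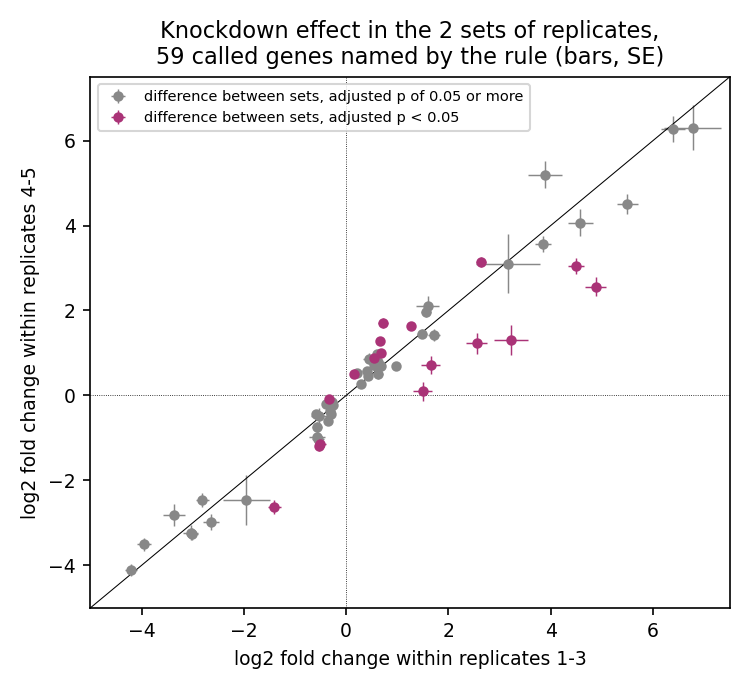
Log2 fold change within replicates 1 to 3 (horizontal) and within replicates 4 and 5 (vertical) for the 59 called genes named by the rule, with SE as bars, a line of equality, and purple points where the difference between the sets was called. The genes were chosen by a call over all 10 libraries, which favours equal signs, and named genes without such a call are not drawn. AGBE lies at 1.49 and 0.10.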

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

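The tests of vector sequence, of muscle RNA, of the spread among tissue lists, of the length correction and of neighbours counted once were chosen after the result was seen, as was the division into sets. The bound on the quartiles of the muscle list was added after its median was known, and without it muscle RNA would be argued against.

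Single libraries stood apart from the other 4 of their group in 6 of 138 tests of named genes, where chance alone gives about 1 in 20. COX7A was at 129.1 CPM in control replicate 3 against 141.3 to 144.7 in the others. daw was at 34.8 CPM in knockdown replicate 1 against 26.6 to 28.6. Hsc70-3 was at 1020.5 CPM in control replicate 4 against 863 to 904. Atg13 was at 81.7 CPM in knockdown replicate 5 against 69.1 to 72.4. Oatp58Db was at 31.5 CPM in knockdown replicate 3 against 34.9 to 35.6. Syx1A was at 36.3 CPM in knockdown replicate 4 against 43.9 to 46.7.

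Splits of the 10 libraries into 5 and 5 were compared with the real one, in 100 of the 126 possible. For each of the counts of called, higher, lower, and at least 2-fold higher or lower genes, only 1 split, the real one, reached the real count. That share of the 100 lies under the bound of 0.05 set in advance. Free splits ignore the numbering and the sets of replicates, and every other split mixes control and knockdown libraries on each side. The share alone therefore does not exclude chance. The real counts against the highest other split were 2317 against 148, 1549 against 132, 768 against 132, 198 against 21 and 48 against 21. Of 12 drawn splits that part all 5 numbered pairs, the real one alone called any gene in edgeR, and the others mix control and knockdown libraries on each side. These 12 are too few for a share under 0.05, so a pairing by number would leave no such test. The split with 148 calls has every library of replicates 4 and 5 on the same side, as have 4 other splits that called 0 genes. For the 15 gene lists called by camera at the preset correlation, 28 splits called as many, the highest other being 19, so chance cannot be excluded for that number.

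The first pattern weighed is the 2317 genes called between the groups. Sequencing depth is argued against, since 2309 genes were called after thinning, and so is a length trend as the whole cause, since 2812 were called with each library's trend removed, although the correlation of log2 change with exon length across genes was 0.15, between the bounds set in advance. A different share of reproductive tract RNA remains open for part of the pattern, because the accessory gland median of -0.29 passed the bound of 0.2 set in advance for it. As the whole cause it is argued against, because medians of the 8 cell type lists outside that tract spread over 1.03 log2 units. That was more than when genes were permuted among lists (permutation p = 0.00134, with genes not independent replicates). The ends were 4 oenocyte markers (-0.57) and 12 hemocyte markers (0.46), and permuting genes ignores correlation within a list. Camera with an estimated correlation called neither list (adjusted p = 0.594 and 0.374). By fry the oenocyte markers were lower (adjusted p = 0.00706) and the hemocyte markers higher (adjusted p = 0.0015). The verdict rests on these 2 lists. Alleles linked to the insertion cannot be told apart from the knockdown, since the control lacked the transgene. The sources disagree on the chromosome that carries it, so that no arm could be named in advance. For genes changed at least 2-fold, the odds ratio on arm 2R was 1.80 (95% interval 1.35 to 2.39, Fisher exact test adjusted p = 0.000328). It lay between the bounds set in advance. The odds ratio was 1.24 (0.84 to 1.79) when neighbours within 100 kb counted once. Linked alleles could change neighbouring genes together, so that lower value does not argue against them.

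The second pattern is the rise of heat shock genes. Vector sequence counted as Hsp70 is argued against as the whole cause, since the 8 members outside Hsp70 had a median log2 change of 1.17 and 7 of them were higher. Handling of only 1 set of replicates is argued against, since the median was 2.39 in one set and 2.58 in the other, although the size differed between the sets in 6 of the 12 members. A response to the hairpin transgene itself, a difference in handling between the groups, and an effect of lower Mef2 all stay open and untested, since no library carried another hairpin.

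The third pattern is a difference between groups of replicates, in that the knockdown effect differed between replicates 1 to 3 and replicates 4 and 5 in 2613 genes by an interaction test in edgeR. The change was larger in replicates 4 and 5 for 2339 of them, while 663 of the 2317 genes called over all libraries were among the 2613. Picking genes by this test favours a larger size in the less precise set, here 2 libraries per group. Fits of each set alone called 3536 genes in replicates 1 to 3 and 3843 in replicates 4 and 5. Mef2 itself went the other way, at -0.34 within replicates 1 to 3 and -0.09 within replicates 4 and 5. The larger changes therefore did not go with a larger fall in Mef2 counts. Depth is argued against, with 2455 genes after thinning. The count was 1652 without control replicate 1, 1293 without control replicate 2, and 1556 and 1628 without knockdown replicate 2 or 3. It was 816 without control replicate 5, 966 without control replicate 4 and 4260 without knockdown replicate 4. Leaving out replicate 4 or 5 leaves 1 library of that group in its set, so such counts rest on a single library there. A different share of muscle RNA cannot be told apart, because the muscle list had a median interaction of -0.0496 but its members went both ways, with quartiles of -0.35 and 0.08. A different time of collection cannot be told apart, because 33.3% of only 9 clock genes differed against 18.8% of all genes, between the bounds set in advance, and no biological explanation was tested, since the labels give no difference between the sets.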

How the results depend on the processing

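The set covariate, the fits within sets, thinning and the length correction were chosen after seeing the data. Both directions of change were found under every alternative run. Counts of higher genes ranged from 1301 to 1905 over the scalings, filters and tools apart from quality weights, which gave 2164. Genes lower numbered 1306 with the DESeq2 Wald test (273 genes without an adjusted p), 1547 with voom quality weights, 2084 with the set covariate (2687 higher), 1386 in replicates 1 to 3 alone (2150 higher) and 2011 in replicates 4 and 5 alone, where only 1832 were higher, so the excess of higher genes turned round. Genes at least 2-fold lower numbered 26 with CPM of at least 1 in 5 libraries, where fewer genes were tested, and 165 in replicates 4 and 5 alone. Lists called by camera fell from 15 to 1 with an estimated correlation, and fry called 11. Fry called JAK-STAT (adjusted p = 0.0386) and the check list (adjusted p = 0.00528), which camera had not. It did not call endoplasmic reticulum folding (adjusted p = 0.0731), glycogen (adjusted p = 0.125) or ribosomal proteins (adjusted p = 0.301), which camera had. Nor did it call accessory gland (adjusted p = 0.0724), photoreceptors (adjusted p = 0.0539) or testis (adjusted p = 0.121). Mef2 kept its direction under all alternatives and lost its call in replicates 4 and 5 alone (-0.12), where 4 libraries remain. With 1 library left out, the ranges were 853 to 1612 higher, 414 to 941 lower, 161 to 211 and 43 to 56 at least 2-fold, 14 to 16 lists, -0.29 to -0.21 for Mef2, and 816 to 4260 genes differing between sets. Both ends of the last range come from fits with 1 library of a group left in the set of replicates 4 and 5. With the replicate number as a block, 1819 genes were higher and 1019 lower, 2084 of the 2317 calls were kept, Mef2 was at -0.24, 206 and 54 genes reached 2-fold, and 17 lists were called. Beyond the list results given beside their main values, the block changed no call of a named gene or list. Changes of sign were 0.0025 for roX1 and -0.19 for Mdh1 in replicates 4 and 5 alone, and -0.041 for Nop56 in replicates 1 to 3 alone, none of them called. Except where fewer genes or libraries are named, the cause was not tested. Depth limits the least abundant genes, since the smallest library places 3 counts at 0.0685 CPM.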

Other observations

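All gene families here were grouped by symbol prefix after the data were seen, so their tests describe these libraries only. All 7 tested subunits of the CCT chaperonin, which folds actin and tubulin, were higher in knockdown, with a median log2 change of 0.66 that was 0.48 within replicates 1 to 3 and 0.90 within replicates 4 and 5. Of 17 aminoacyl-tRNA synthetases, 13 were higher and none lower (median 0.43, 0.27 and 0.68 in the sets). Both differed between the sets in most members, 7 of 7 and 15 of 17. By camera over 20 families the adjusted p was 1.77e-06 and 2.45e-07, but with an estimated correlation adjusted p = 0.443 for each. Glutathione transferases had 17 of 35 members higher and 2 lower, UDP-glycosyltransferases 9 of 34 higher and 1 lower, and proteasome subunits none of 46 higher and 1 lower. Within replicates 1 to 3, 10 proteasome subunits were higher and none lower, and within replicates 4 and 5, 13 were higher and 17 lower, with 9 called in the interaction.

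Between replicates 4 and 5 and replicates 1 to 3, averaged over the groups, 3489 genes were called in edgeR. The median log2 difference was -0.52 for muscle markers and -0.45 for oxidative phosphorylation, with no list test and no value within each group. The fat body list had a median knockdown change of 0.51 within replicates 1 to 3 and -0.24 within replicates 4 and 5, and its interaction was called by camera (adjusted p = 0.000327, but adjusted p = 0.192 with an estimated correlation). In ribosome biogenesis, 12 of 13 genes were higher within replicates 4 and 5 and none within replicates 1 to 3. The interaction was called in 10 of them.

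whe and lcs, the genes with the largest falls under the rule, are neighbours on chromosome X, 5.02 kb apart.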
